A study of Mus musculus with 8 samples.

How the data were processed

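Gene expression was measured by mRNA sequencing in 8 whole placentas of male mouse fetuses at 17.5 days post coitum. Of these, 4 came from fetuses that inherited a Klf14 knockout allele from the mother (matKO) and 4 from wild-type (WT) fetuses. Per the labels' protocols, libraries were made with an Illumina TruSeq kit after poly-A capture, sequenced from both ends, and carry first-strand orientation. Per the labels' protocols, RNA was extracted with Trizol from WT replicates 1 and 2 and matKO replicates 1 and 2, all of litter 6055. RNA of the other placentas was extracted on RNeasy columns, with WT replicates 3 and 4 from litter 6188 and matKO replicates 3 and 4 from litter 6232. Extraction method was therefore balanced against genotype but confounded with litter, and among the RNeasy libraries litter and genotype cannot be told apart.

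The authors deposited a single table of 55536 genes. Per the file headers it holds a normalized signal per gene and library, together with the authors' DESeq2 result columns: a mean, a log2 fold change, its standard error, a test statistic (score), a p-value and an adjusted p-value. The submitters' processing notes name Trim Galore, STAR 2.7.0e, featureCounts, HTSeq and DESeq2, with no role or order, and the use of strand in counting is not given in the sources used here. The genome build is not given in the sources used here either. All 55536 gene identifiers and all 55536 symbols of the table were equal to those of GENCODE release M21 on the mouse GRCm38 primary assembly, and coordinates are given from that annotation. In every library, 100% of the deposited values were whole multiples of that library's smallest value within a relative tolerance of 1e-06, so that each value is a read count divided by 1 factor per library. Dividing by the smallest value recovered whole reads, which summed to 28.8 to 44.6 M reads (M for 1e+06) per library. No reads or unnormalized counts were analysed here beyond these recovered reads.

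The gene tests fixed before the data were examined were edgeR quasi-likelihood tests on raw counts. Because the table holds normalized values, the test planned for that case was used: limma 3.58.1 with a trend on log2(value + 1), on the 16378 genes with a mean value of at least 10, with extraction method as an additive term and Benjamini-Hochberg adjusted p under 0.05. Fold changes are on this log2(value + 1) scale, which understates changes of low genes. edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr), the test first planned for raw counts, was run on the recovered reads as an added alternative and called 7 genes. The 3 genes called in the main comparison come from the limma test planned for normalized values. Gene lists were tested with limma's camera at a preset correlation of 0.01, then with an estimated correlation, and with fry. fry asks whether a list's genes move on balance in 1 direction, its mixed form whether they change in either direction, and neither compares a list with other genes. DESeq2 1.42.0, R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were also used. The tests named next were checked on simulated data drawn from the means and spreads of these libraries. For the matKO against WT comparison over 16378 genes, limma recovered 77% of genes changed by a simulated fold of 2 and 93% of those changed by a fold of 4, with 6.59% false calls. DESeq2 recovered 77% and 93%, with 11.9% false calls. Within the Trizol litter limma recovered 57% and 87%, and between the RNeasy litters 65% and 85%, where edgeR recovered 65% and 86%. For the difference of the genotype effect between the extraction sets limma recovered 42% and 78%, edgeR 42% and 76%, and DESeq2 50% and 76%. False calls were 11.8% between the RNeasy litters by limma, and 11.1%, 10.6% and 19.2% for that difference by limma, edgeR and DESeq2. With 1 of 28 lists raised by a simulated fold of 1.5, camera with the preset correlation, camera with an estimated correlation and fry each called that list and no other. The simulated genes varied independently, while the estimated correlation within the lists called for genotype was 0.03 to 0.83. This check therefore cannot show how often camera with the preset correlation calls lists falsely in these libraries. Variation shared by many genes of a library was not simulated either, so the recovery and false calls of the gene tests may not hold for these libraries.

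The genes named in the text were fixed by a rule before the data were examined. Klf14 is always named. Genes past the threshold are named up to 12 in each direction, and the genes with the next smallest p fill up to 20 and are given as values that did not pass. From each of 29 gene lists fixed before the data were examined, up to 4 members with the smallest p are named, and for extraction the 5 genes with the smallest p in each direction. The lists cover the Klf14 neighbourhood, KLF and SP factors, genes tied to KLF14 in human adipose tissue or cultured cells, maternally and paternally expressed imprinted genes, the prolactin family, pregnancy-specific glycoproteins and placental Ceacams, placental cathepsins, spongiotrophoblast, glycogen trophoblast, trophoblast giant cell, and syncytiotrophoblast and labyrinth markers, and nutrient transporters. They also cover fetal endothelium, mesenchyme and matrix, smooth muscle, decidual stroma, uterine natural killer cell, macrophage, neutrophil, erythroid and yolk sac endoderm genes. The remaining lists are immediate early and heat shock, hypoxia and glycolysis, interferon response, cholesterol and lipid synthesis, mitotic cell cycle, mitochondrially encoded and sex-linked genes. The sex-linked genes check the labels and were not tested as a list, which leaves 28 tested lists.

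Replicate numbers are shared between genotypes, so it was checked whether they pair the samples. Deviations from the genotype means correlated between same-numbered libraries at 0.46 to 0.60, but at 0.52 to 0.64 between libraries of the same extraction with other numbers. Fitting extraction and genotype itself draws correlations between libraries of the same extraction and unlike genotype negative. After that fit, same-numbered libraries correlated at -0.38 to -0.10, and those of the same extraction with other numbers at -0.22 to -0.01. The pairing therefore follows the split into Trizol and RNeasy libraries, which the numbers share and in which extraction and litter cannot be told apart. Replicate pairs within a genotype and extraction set differed by far more than sampling noise (chi-square of 11.5 to 56.7 per gene), so all 8 were kept as separate replicates. Placentas of a litter are separate fetuses.

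The alternatives tried were genotype alone, a replicate block or a litter term in place of extraction, DESeq2, limma-voom, upper quartile and TMM factors, no filter or a mean of at least 50, pseudocounts of 0.5 and 5, a threshold of 0.10, each extraction set alone, and leaving out each library in turn. With a litter term the genotype estimate comes from the Trizol litter alone, since each RNeasy litter holds 1 genotype. Some alternatives were added after the data were seen: limma with TMM factors, DESeq2 with genotype alone, the smooth muscle level as a covariate, a GC content and length correction, and thinning of reads. The use of edgeR on recovered reads was also added then, although edgeR was the test first planned for raw counts. Genes of near-identical families (prolactins, pregnancy-specific glycoproteins, globins, granzymes, ribosomal RNA and mitochondrial genes) may share reads, and genes overlapping an antisense gene cannot be separated from it where counting ignored strand, so their values are uncertain.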

Results

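The dataset compared placentas of male mouse fetuses near term that lacked a maternal copy of Klf14 with wild-type placentas, 4 of each. Klf14 encodes a zinc-finger transcription factor of the KLF family and is an imprinted gene expressed from the maternal allele, so a knockout allele inherited from the mother removes the active copy. The question addressed by the design is which placental transcripts change when that copy is missing. Recovered totals were 35.6, 29.9, 39.4 and 44.0 M reads (M for 1e+06) in WT replicates 1 to 4 and 29.9, 28.8, 38.2 and 44.6 M in matKO replicates 1 to 4. The libraries separated first by extraction, as the first principal component held 58.4% of the variance and parted the Trizol from the RNeasy libraries.

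**Figure D1:**
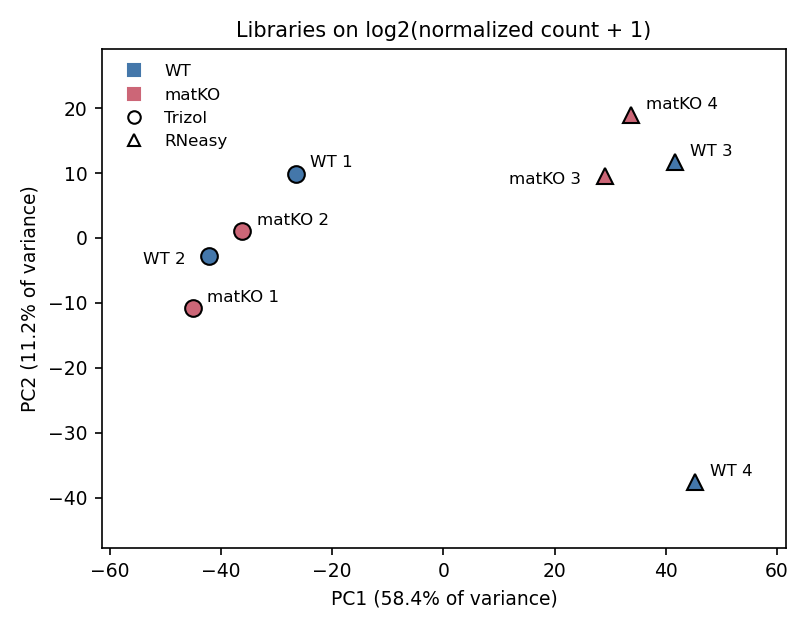
Principal components of log2(normalized count + 1) over 16378 genes, with each point a library, colour giving genotype and shape giving extraction method. Trizol and RNeasy libraries lie on opposite sides of the first component (58.4% of variance), and WT replicate 4 lies apart on the second (11.2%).

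The targeted gene, Klf14 (ENSMUSG00000073209, chromosome 6, 30956023 to 30959078, minus strand, GRCm38, a protein-coding gene with 1 exon), was measured first as a check of the labels. Its normalized read counts were 548, 616, 294 and 269 in WT replicates 1 to 4 and 6.79, 5.97, 1.94 and 6.63 in matKO replicates 1 to 4. The mean fell from 432 ± 176 to 5.33 ± 2.29 (SD, n = 4 each), which leaves 1.24% of the WT level. The log2 fold change was -6.10 with an SE of 0.27 (limma adjusted p = 5.8e-06), and no matKO library reached the lowest WT library. The fold was -6.30 within the Trizol litter and -5.90 between the RNeasy litters.

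Beyond Klf14, a collagen gene and an elastic fibre gene rose in matKO placentas. Col26a1, which encodes a collagen chain (chromosome 5, 136741759 to 136883209, minus strand), rose from 20.2 ± 4.06 to 87.6 ± 16.2 normalized counts, a log2 fold change of 2.07 with an SE of 0.19 (limma adjusted p = 0.0036). Fbln5, which encodes fibulin 5, an extracellular protein needed for elastic fibre assembly (chromosome 12, 101746565 to 101819055), rose from 465 ± 124 to 901 ± 186, a log2 fold change of 0.97 with an SE of 0.11 (limma adjusted p = 0.014). For both genes all 4 matKO libraries lay above all 4 WT libraries. In all, 3 of 16378 genes passed, 2 higher and 1 lower, 23 lay under an adjusted p of 0.10, and 824 lay under an unadjusted p of 0.05, of which 592 were higher and 232 lower in matKO. The number of calls depended on the tool and the libraries: DESeq2 with the same terms called 96 genes, edgeR 7, a replicate block 5 and a litter term 1, and leaving out single libraries gave 1 to 34. Without matKO replicate 1, 2 or 3, Klf14 alone passed, and Fbln5 did not pass without matKO replicate 4 either (limma adjusted p = 0.073).

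**Figure D2:**
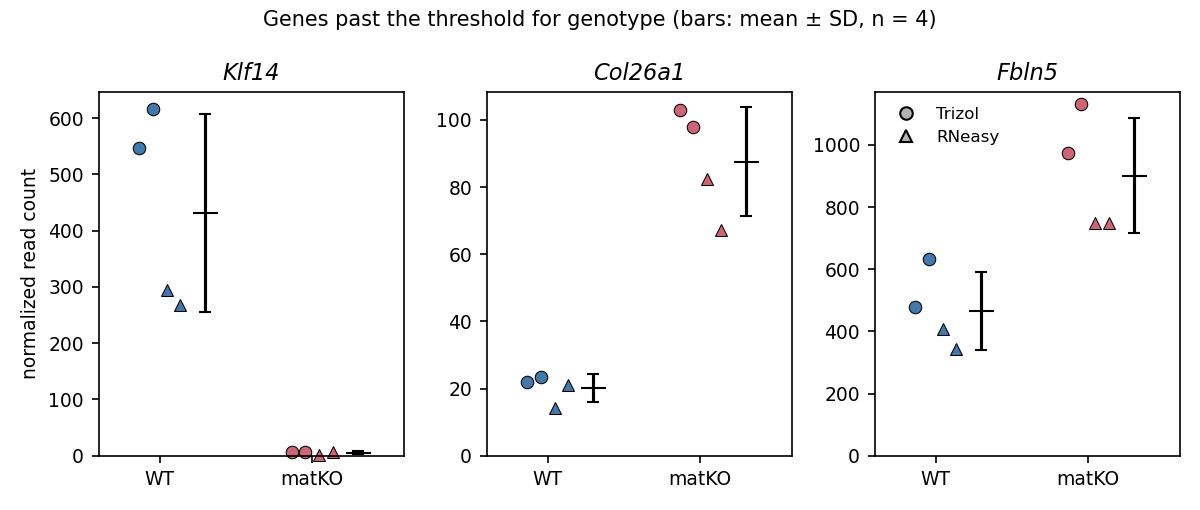
Normalized read counts of Klf14, Col26a1 and Fbln5 in each library, with circles for Trizol, triangles for RNeasy and black bars for mean ± SD (n = 4). The genotypes do not overlap in any of the 3 genes, with Klf14 at 269 or more in WT and at 6.79 or less in matKO.

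The 17 genes with the next smallest p were all higher in matKO, but none passed the threshold (limma adjusted p of 0.059 to 0.098). Several encode secreted signals or matrix proteins. The normalized count was 15.7 ± 7.13 in WT and 94.9 ± 56.1 in matKO for the growth factor Gdf10, 124 ± 27.9 and 261 ± 37.6 for the guidance ligand Slit2, 54.7 ± 21.9 and 137 ± 28.6 for the Wnt antagonist Dkk2, and 24.7 ± 10.6 and 107 ± 36.5 for Nell1, a secreted protein. Among matrix genes, log2 fold changes were 1.02 for Col8a1, 0.89 for Col11a1 and 0.85 for the microfibril protein Mfap2. Cell surface genes in this set were Igdcc4 at 1.03, the natriuretic peptide receptor Npr3 at 0.69, the adrenoceptor Adra1d at 2.27 and the Wnt co-receptor Ptk7 at 0.46. The others were Olfm2 at 1.10, the adenylate cyclase Adcy2 at 1.40, Begain at 2.51, the muscle glycogen phosphorylase Pygm at 0.82, the kinase inhibitor Pkia at 1.13 and the noncoding Gm26917 at 1.50. Gm26917 lies beside a ribosomal RNA gene on chromosome 17 and ranged widely within genotypes (4774 ± 3963 in WT and 11567 ± 5096 in matKO), so its value is uncertain. Over all genes tested, 189 had no overlap between genotypes (1.15%). The 2.86% that random splits of 4 against 4 give assumes interchangeable libraries. Extraction differences within each genotype make overlap more likely, so these shares cannot be compared.

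**Figure D3:**
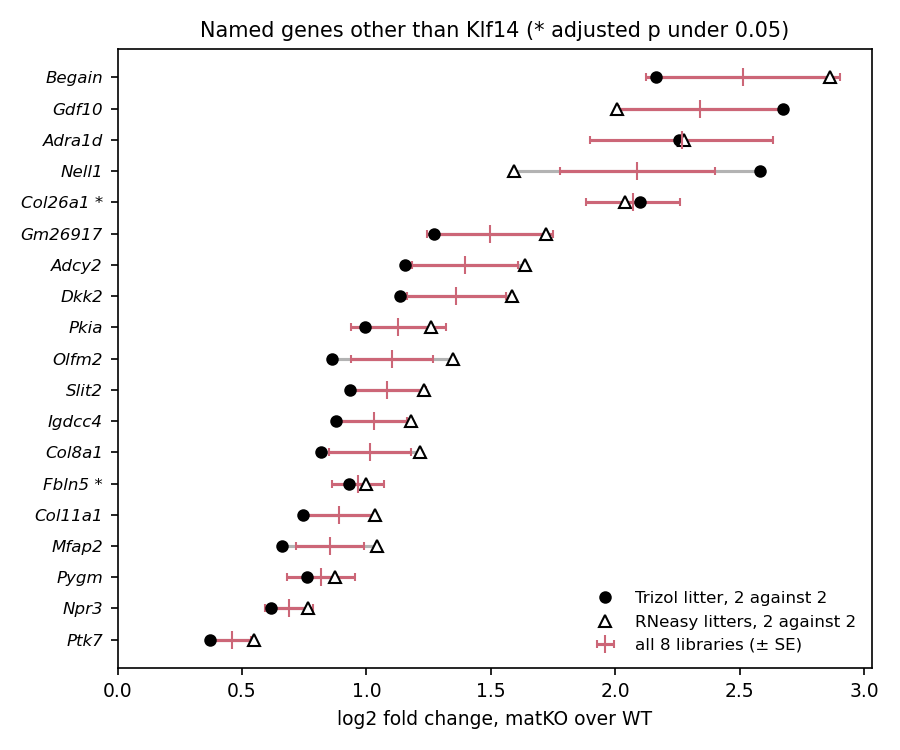
Log2 fold changes of the 19 named genes other than Klf14, within the Trizol litter (circles), between the RNeasy litters (triangles) and over all 8 libraries (red, ± SE). The genes were chosen by p over both sets together, and those marked with an asterisk, Col26a1 and Fbln5, are past the threshold.

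The authors' deposited table called 17 genes at an adjusted p under 0.05, 13 higher and 4 lower, with Klf14 at a log2 fold change of -6.34 and Col26a1 at 2.12. All 17 had the same direction in the limma fit, in which 3 passed 0.05 and 13 passed 0.10. DESeq2 with genotype alone on the recovered reads gave every log2 fold change and p-value of the authors' deposited table within 1e-05. It called 10 genes with its own choice of 24699 genes to adjust over, and 17 when the adjustment covered the 19637 genes adjusted in the authors' deposited table.

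Among the fixed gene lists, all 8 smooth muscle markers were higher in matKO, with a mean log2 fold change of 0.51 (limma camera adjusted p = 3.5e-08; adjusted p = 0.285 with an estimated correlation), although none of the 8 passed over all genes and 5 rose when adjusted over the list alone. The log2 fold change was 0.86 for Tagln, 0.52 for Acta2, 0.89 for Actg2 and 0.59 for Myh11, all parts of the contractile machinery or its regulation. Mesenchyme and matrix markers had a mean of 0.17 (11 of 12 higher, camera adjusted p = 0.0013; adjusted p = 0.455 with an estimated correlation), and 2 of them, Col1a2 at 0.38 and Col3a1 at 0.44, passed when adjusted over the list alone. Postn was at 0.22 and Fbn1 at 0.25. Both lists were also lower in RNeasy than in Trizol libraries, by -1.34 and -0.78 on average. The mesenchyme call was also lost with genotype alone, with a litter term (mean 0.11) and without matKO replicate 3 (0.08), and the smooth muscle mean was 0.34 with a litter term.

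Macrophage markers were lower in matKO, with a mean of -0.45 and 9 of 10 members lower (camera adjusted p = 4.1e-06; adjusted p = 0.388 with an estimated correlation). Cd163, a scavenger receptor of tissue macrophages, was 85.5 ± 9.27 in WT and 44.3 ± 9.73 in matKO and was the single member that passed when adjusted over the list alone. The complement genes C1qa, C1qc and C1qb were at -0.67, -0.60 and -0.58. The macrophage call was lost with a litter term (mean -0.19), and the mean was -0.30 without WT replicate 3. Fetal endothelium markers had a mean of -0.10 with 9 of 12 lower (camera adjusted p = 0.0077; adjusted p = 0.388 with an estimated correlation). Kdr, the main receptor for VEGF, was 1733 ± 141 in WT and 1306 ± 162 in matKO and passed over its list alone, while Pecam1, Tie1 and Tek were at -0.15, -0.21 and -0.19. The endothelium call was lost without WT replicate 2 (mean -0.06) and without matKO replicate 2 (-0.08). Mitochondrially encoded transcripts had a mean of -0.20 with 10 of 12 lower (camera adjusted p = 0.0025; adjusted p = 0.588 with an estimated correlation), with mt-Nd6 at -0.34, mt-Nd5 at -0.33, mt-Nd4 at -0.26 and mt-Co2 at -0.32. That list was at 0.04 within the Trizol litter and at -0.44 between the RNeasy litters, and its call was lost without WT replicate 4 (mean -0.08), without matKO replicate 4 (-0.14) and with genotype alone.

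The other lists past the preset threshold were higher in matKO. Mitotic cell cycle genes had a mean of 0.26 with 15 of 16 higher (camera adjusted p = 4.1e-06; adjusted p = 0.455 with an estimated correlation), including Top2a at 0.41, Ccnb2 at 0.43, Mki67 at 0.38 and Cdk1 at 0.32. Erythroid genes had a mean of 0.29 with 10 of 11 higher (camera adjusted p = 8.1e-06; adjusted p = 0.455 with an estimated correlation), and 5 passed over the list alone, among them Hba-a2 at 0.48, Alas2 at 0.35, Hbb-bt at 0.46 and Hba-a1 at 0.48. The erythroid call was lost with a litter term (mean 0.12). Haemoglobin transcripts took 1.53% to 2.79% of reads in Trizol libraries and 0.663% to 1.09% in RNeasy libraries. Uterine natural killer cell genes had a mean of 0.47 with 7 of 7 higher (camera adjusted p = 0.00033; adjusted p = 0.530 with an estimated correlation), including Gzmb at 0.85, Prf1 at 0.57, Gzme at 0.24 and Gzmd at 0.45. That mean was 0.24 without WT replicate 3, 0.74 without WT replicate 4 and 0.25 with no filter. Of the 11 fixed members, Gzma, Klrk1, Ncr1 and Klrb1c lay under the minimum mean, at 3.39, 1.40, 0.53 and 0.26. The 7 measured were Prf1 and granzymes, with an estimated correlation of 0.83, so the call does not cover the receptor genes of these cells. Yolk sac endoderm markers had a mean of 0.39 with 10 of 11 higher (camera adjusted p = 0.0023; adjusted p = 0.588 with an estimated correlation), with Spink1 at 0.67, Ttr at 0.56, Apob at 0.67 and Cubn at 0.45. The yolk sac mean was 0.72 without matKO replicate 1 and 0.08 without matKO replicate 2, which ended the call. Glycogen trophoblast markers had a mean of 0.19 with 11 of 11 higher (camera adjusted p = 0.019; adjusted p = 0.588 with an estimated correlation), with Gbe1 at 0.17, Ncam1 at 0.41, Cdkn1c at 0.12 and Prl7b1 at 0.47. The glycogen trophoblast call was lost with a litter term (mean 0.05) and without WT replicate 1 (0.03), WT replicate 4 (0.10), matKO replicate 3 (0.12) or matKO replicate 4, and the mean was 0.40 without WT replicate 2. Hypoxia and glycolysis genes had a mean of 0.10 with 10 of 12 higher (camera adjusted p = 0.046; adjusted p = 0.485 with an estimated correlation), with Ankrd37 at 0.50, Ndrg1 at 0.12, Adm at 0.12 and Aldoa at 0.10. The hypoxia call was lost with genotype alone, the replicate block (camera adjusted p = 0.0509) or a litter term, and on leaving out any library but WT replicate 2 or matKO replicate 1, with means down to 0.05. In all, 11 of 28 lists passed with the preset correlation, 8 higher and 3 lower, none passed with an estimated correlation (lowest adjusted p = 0.285) or by fry (lowest adjusted p = 0.188), and 3 passed by the mixed form of fry. These 3 were the Klf14 neighbourhood, fetal endothelium and macrophage lists. The neighbourhood list includes the knocked-out gene itself, so its pass does not speak to the neighbouring genes.

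**Figure D4:**
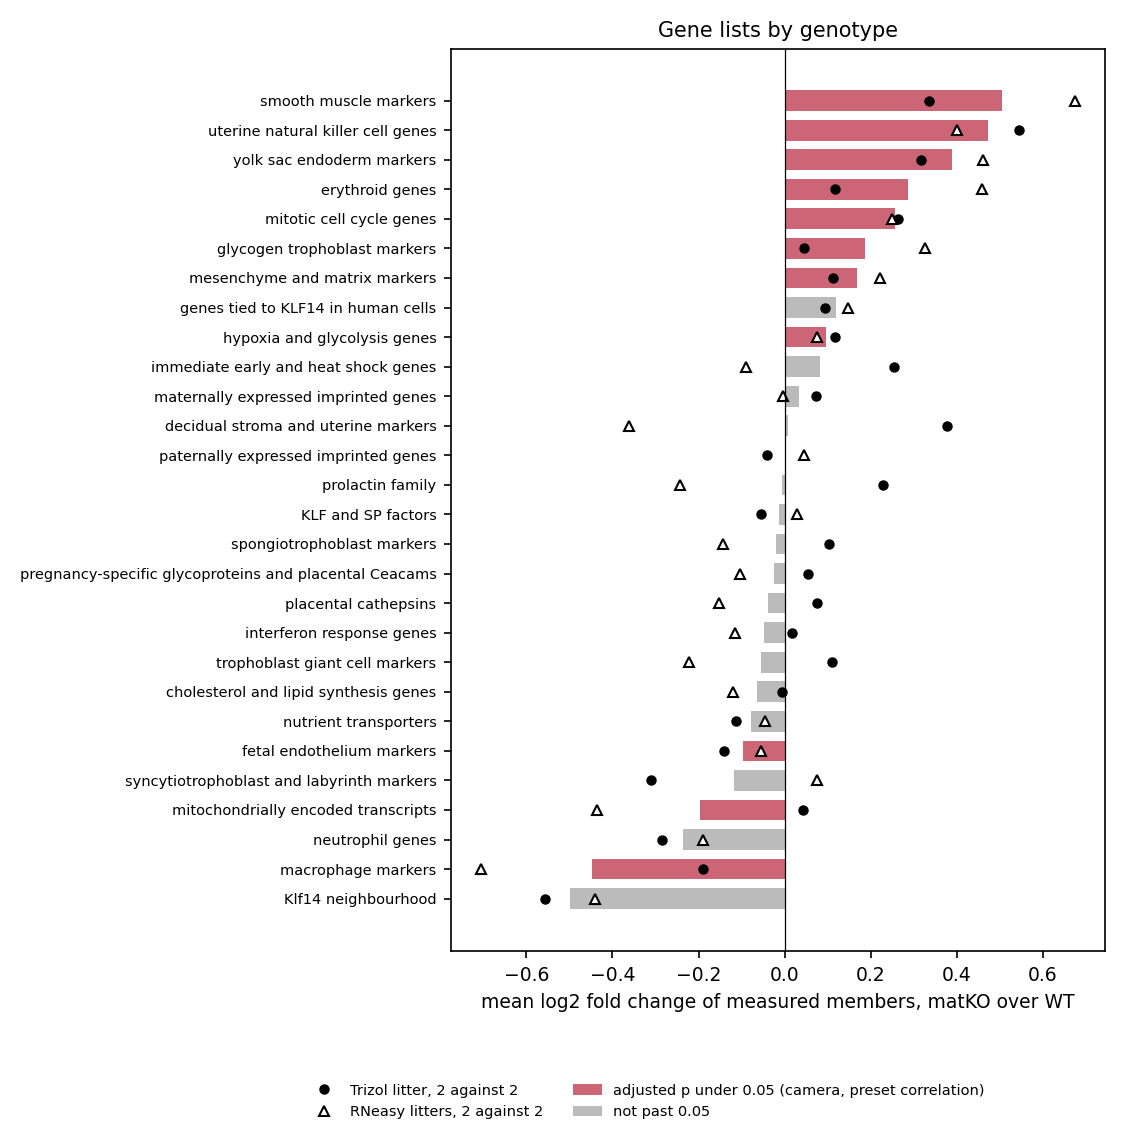
Mean log2 fold change (matKO over WT) of the measured members of 28 gene lists (bars), with the mean within the Trizol litter (circles) and between the RNeasy litters (triangles). Red bars mark the 11 lists with a camera adjusted p under 0.05 at the preset correlation, from smooth muscle at 0.51 to macrophage markers at -0.45.

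Imprinted genes did not pass as lists. Of 35 maternally expressed imprinted genes other than Klf14, none passed over all genes (camera adjusted p = 0.308), and their median and mean differed in sign, at -0.03 and 0.03, with Phactr2 at 0.33 and Meg3 at 0.35. Of 29 paternally expressed genes, none passed (camera adjusted p = 0.888), with a median of -0.03 and a mean of 0.00, Nnat at 0.43 and Mest at 0.28. Mest, the paternally expressed neighbour of Klf14, rose from 11937 ± 2113 to 14420 ± 1778 when adjusted over the Klf14 neighbourhood alone (adjusted p = 0.022) and not over all genes, and it overlaps Copg2 on the other strand. Cpa4 was at 0.60 and Copg2 at 0.10. The neighbourhood list held a median of 0.06 and a mean of -0.50, which includes Klf14 itself (camera adjusted p = 0.888). Other KLF and SP factors had a mean of -0.01 (20 measured, none passed, camera adjusted p = 0.873), with Klf5 at 0.14 and Klf7 at -0.11. Genes tied to KLF14 in human adipose tissue or cultured cells had a mean of 0.12 (10 measured, none passed, camera adjusted p = 0.706), with Slc7a10 at 1.01 and Tgfbr2 at -0.17.

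Trophoblast lists other than glycogen trophoblast did not pass. Means were -0.01 for the prolactin family (camera adjusted p = 0.808), -0.03 for pregnancy-specific glycoproteins and placental Ceacams (0.308), -0.04 for placental cathepsins (0.557), -0.02 for spongiotrophoblast markers (0.643), -0.06 for trophoblast giant cell markers (0.706), -0.12 for syncytiotrophoblast and labyrinth markers (0.082) and -0.08 for nutrient transporters (0.082). None of their members passed over all genes or over its list alone. Examples are the prolactins Prl8a1 at 0.58 and Prl3d1 at -0.63, Psg17 at -0.19, Ceacam15 at 0.38, the cathepsins Ctsm at -0.22 and Cts3 at -0.21, Ascl2 at 0.33, Hand1 at -0.16, Gcm1 at -0.49, the glucose transporter Slc2a3 at -0.45 and the amino acid transporter Slc7a8 at -0.20. Decidual stroma and uterine markers had a median of -0.03 and a mean of 0.01 (camera adjusted p = 0.888), with Bmp2 at 0.35 and Adamts5 at 0.21. Without WT replicate 4 the decidual mean was 0.34 and passed (camera adjusted p = 4.0e-06; adjusted p = 0.332 with an estimated correlation). Without that library the preset correlation also called prolactins (mean 0.15), syncytiotrophoblast and labyrinth markers (-0.23), nutrient transporters (-0.11) and immediate early genes (0.13), with an adjusted p of 0.486 to 0.861 at an estimated correlation. Means were -0.24 for neutrophil genes (camera adjusted p = 0.148), 0.08 for immediate early and heat shock genes (0.109), -0.05 for interferon response genes (0.434) and -0.06 for cholesterol and lipid synthesis genes (0.124). In these lists the immediate early gene Dusp1, at 0.35, passed over its list alone, while Ier2 was at 0.27, Ngp at -0.67, Camp at -0.80, Rsad2 at -0.26, Mx1 at -0.41, Scd2 at -0.26 and Scd1 at -0.22. Of the sex-linked genes, the mean of Ddx3y, Eif2s3y, Kdm5d and Uty was 497 to 1024 in every library, and Kdm5d was at -0.30 and Eif2s3y at -0.12 between genotypes.

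The genotype comparison was repeated within the Trizol litter, the only litter with both genotypes, at 2 placentas each. There 3 genes passed in limma, with Klf14 lower and Gdf10 (log2 fold change 2.68, adjusted p = 0.027) and Nell1 (2.58, adjusted p = 0.027) higher. Between the RNeasy litters, where genotype and litter cannot be told apart, limma called 0 genes with 1002 under an unadjusted p of 0.05, and edgeR called 1. With the spread of all 8 libraries, Klf14 alone passed in each set. A difference of the genotype effect between the sets was found for 0 genes by limma (489 under an unadjusted p of 0.05), 0 by edgeR (561) and 0 by DESeq2 (399). Over all genes tested, 50.9% had the same sign in both sets, and the log2 fold changes of the sets correlated at 0.14.

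The extraction sets differed far more than the genotypes. Between RNeasy and Trizol libraries, 7805 of 16378 genes passed, 4087 higher and 3718 lower in RNeasy. The transferrin receptor gene Tfrc was 9395 ± 1925 in Trizol and 67973 ± 11652 in RNeasy libraries, a log2 difference of 2.86 with an SE of 0.11 (limma adjusted p = 4.5e-07). CT030661.1, Far1, Tmed5 and Bclaf3 were higher in RNeasy by 2.91, 1.36, 1.79 and 1.67. The ribosomal RNA gene CT010467.1 was at -5.68, the imprinted gene Nnat at -2.90, the matrix genes Bgn and Tnc at -1.39 and -2.39, and Syn3, which overlaps Timp3 on the other strand, at -4.98. Prolactin family genes were higher in RNeasy libraries, with a mean of 0.83 and 14 of 23 past the threshold. Pregnancy-specific glycoproteins and placental Ceacams were higher by 0.80 (18 of 21) and spongiotrophoblast markers by 0.65 (10 of 12). Smooth muscle, erythroid, mesenchyme, immediate early and endothelium genes were lower on average, by -1.34, -1.15, -0.78, -0.62 and -0.52. These were the 8 lists past the preset threshold for extraction, of which 0 passed with an estimated correlation (adjusted p of 0.370 to 0.725), and 11 lists passed by fry. Mitochondrial transcripts took 1.03% to 1.27% of reads in Trizol and 1.64% to 2.45% in RNeasy libraries. Extraction method and litter cannot be told apart in this comparison.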

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

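Tests chosen after the result was seen were the splits for the genotype gene count, the Trizol litter test of Col26a1 and Fbln5, and the tests on WT replicate 4, while the smooth muscle covariate, the GC content and length correction and the thinning were added after the data were seen.

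The first pattern is the rise of Col26a1 and Fbln5 in matKO placentas, weighed because litter and genotype coincide among the RNeasy libraries. Within the Trizol litter, which holds both genotypes, the log2 fold change was 2.10 (95% interval 1.47 to 2.74) for Col26a1 and 0.93 (0.58 to 1.28) for Fbln5, with the spread of all 8 libraries. Both genes were chosen by p over all 8 libraries, the Trizol libraries included, so these intervals cannot decide against a litter difference among the RNeasy libraries. Tested in the Trizol litter alone, neither gene passed (limma adjusted p = 0.081 for Col26a1 and 0.612 for Fbln5). With the smooth muscle level as a covariate, Col26a1 kept 96.1% and Fbln5 74.3% of the log2 fold change. The lower 95% bounds were 1.04 and 0.22. This fit cannot decide against more smooth muscle tissue in matKO libraries as the cause, since both genes were chosen from the same libraries. Neither call held in that fit (limma adjusted p = 0.9999 for both). The SE rose from 0.19 to 0.42 for Col26a1 and from 0.11 to 0.22 for Fbln5, whose log2 fold change also moved from 0.97 to 0.72. Of 34 splits of the 8 libraries that could be fitted with extraction, 3 gave at least 3 genes, the real one included, so chance cannot be excluded for the count. The highest other split, WT replicates 1 and 3 with matKO replicates 3 and 4 against the rest, gave 131, and its cause was not tested. Of the 8 splits that part all 4 same-numbered pairs, the other 7 gave 0 genes. That subset cannot exclude chance, since 8 splits are too few and the numbers did not pair the samples once extraction was fitted. Loss of the maternal Klf14 copy remains open as the biological explanation.

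The second pattern is the difference between the Trizol and RNeasy libraries. Of 34 splits, 1, the real one, gave 7805 genes and the highest other gave 0. Every other split put Trizol and RNeasy libraries on both sides, which left their difference in the spread and made low counts likely. The splits also treat placentas of a litter as independent, so they cannot exclude chance at the level of litters. The RNeasy litters differed from each other in 1 gene, Klf14. Each differed from the Trizol libraries of its genotype in many more, 5005 (WT) and 4607 (matKO) genes. A litter difference of that size was thus absent between the RNeasy litters. A single pair of litters cannot show how far litters ordinarily differ. Higher depth is argued against, since 7695 genes (98.6% as many) passed after every library was thinned to 28800354 reads. A trend on GC content and length cannot be told apart from the other sources: 6007 genes (77.0% as many) passed after its removal, which is under the 90% set beforehand for arguing against it, and 4212 of the 6007 were among the 7805. The log2 differences also correlated across genes with GC content (-0.57) and with log2 length (0.33), so such a trend may account for part of the difference. Something particular to litter 6055 and the extraction itself cannot be told apart, as no litter was extracted both ways.

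The third pattern is that WT replicate 4 stood apart in decidual genes. Of 10 measured decidual markers, 6 were highest of all 8 libraries there, with Pgr at 151 against 7.85 to 43.6 elsewhere and Prl8a2 at 6361 against 1103 to 2244, and Xist was at 316 against 46.0 to 95.3. A female placenta labelled male is argued against by the Y-linked genes, at 1.08 times the mean of the other 3 RNeasy libraries, and depth by matKO replicate 4, of like depth, whose decidual level was -1.18 log2 units from that of WT replicate 4. Maternal decidual tissue in that library, which would bring decidual markers and Xist together, is consistent with these values and stays a hypothesis, with no biological difference in the design to set against it.

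Single libraries lay far from the other 3 of their genotype in 12 of 274 groups tested (4.38%). A chance rate of about 1 in 20 assumes values from a single normal distribution. Each group mixes Trizol and RNeasy libraries, so that rate need not hold here. In matKO replicate 2 the flagged values were Spink1 at 189, Ttr at 1164, Cubn at 1344, Col8a1 at 287 and Tek at 1323. In matKO replicate 3 they were Klf14 at 1.94 and Prl7b1 at 4083, and in matKO replicate 1 Pkia at 67.9 and the mean log2 level of hypoxia and glycolysis genes at 10.9. In WT replicate 4 they were Adamts5 at 427 and Gzmd at 790, and in WT replicate 1 Apob at 1502.

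The genotype effect on 12 lists differed between the extraction sets by camera with the preset correlation, and on 0 lists with an estimated correlation or by fry. The difference (RNeasy less Trizol) in mean log2 fold change was -0.47 for the prolactin family, -0.16 for pregnancy-specific glycoproteins and Ceacams, 0.28 for glycogen trophoblast, -0.33 for giant cell, 0.39 for syncytiotrophoblast and labyrinth, 0.34 for smooth muscle, -0.74 for decidual and -0.52 for macrophage markers. It was 0.34 for erythroid, -0.34 for immediate early, -0.11 for cholesterol synthesis and -0.48 for mitochondrially encoded genes. Adjusted p with an estimated correlation was 0.561 for each of these but cholesterol synthesis, at 0.608. Without WT replicate 4, 9 lists differed by camera with the preset correlation, the decidual difference was -0.0865 (camera adjusted p = 0.325) and the prolactin difference -0.19. The glycogen trophoblast (0.14), giant cell (-0.15), syncytiotrophoblast and labyrinth (0.19) and cholesterol synthesis (-0.07) differences were also lost (camera adjusted p of 0.160 to 0.325). Uterine natural killer cell (0.49) and mitotic (-0.22) genes were newly called, and the mitochondrially encoded difference was -0.30.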

How the results depend on the processing

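The fall of Klf14 kept its direction in every setting and passed in all but 1. Its log2 fold change ranged from -6.42 to -5.86 when each library was left out in turn, and was -6.10 with the replicate block, which pairs same-numbered libraries. Between the RNeasy litters alone it was -5.90 and did not pass (limma adjusted p = 0.111), with 2 libraries each. The 3 genes of the genotype comparison became 1 with genotype alone, 1 with a litter term and 1 with the smooth muscle level as a covariate, 0 between the RNeasy litters, 5 with the replicate block, 5 with a pseudocount of 5, 5 with the GC content and length trend removed, 7 by edgeR, 10 by DESeq2 with genotype alone, 14 with no filter, 23 at an adjusted p of 0.10 and 96 by DESeq2. Leaving out single libraries gave 1 to 34 genes. Limma-voom, upper quartile and TMM factors, a mean of at least 50, a pseudocount of 0.5 and thinned reads gave 3. The cause of these differences was not tested. The replicate block added Cp and Eln, at 0.67 and 0.78, and changed no other call of a gene; its lists numbered 10 against 11, without hypoxia and glycolysis genes (camera adjusted p = 0.0509). The 11 lists were 8 with genotype alone and 10 with a litter term, of which 5 were among the 11, 0 with an estimated correlation and 0 by fry, and 9 to 13 when single libraries were left out. Within the Trizol litter, 3 genes became 1 with the spread of all 8 libraries, and between the RNeasy litters 0 became 1 with that spread and 1 by edgeR. The extraction count stayed within 6007 to 7904. The planned DESeq2 size factors are those of the deposited values and gave no separate result. The alternatives TMM, DESeq2 with genotype alone, the covariate, the GC content correction and thinning were chosen after seeing the data. So was the use of edgeR on recovered reads, although edgeR was the test first planned for raw counts.

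No gene past the threshold turned direction. Among genes that did not pass over all genes, signs turned with a litter term and within the Trizol litter alone, which give the same estimate. These genes were Ascl2 (-0.0329), Aldoa (-0.0376), Mx1 (0.16), Scd2 (0.0185), Scd1 (0.0133), Kdm5d (0.17) and Eif2s3y (0.0294). The sign turned for Adamts5 between the RNeasy litters (-0.175) and for Prl7b1 without WT replicate 1 (-0.0355, against 0.88 without WT replicate 2). With a litter term the mean of mitochondrially encoded transcripts was 0.0419. With the smooth muscle level as a covariate, signs turned for Meg3 (-0.20), Ceacam15 (-0.29), Ctsm (0.0555), Cts3 (0.0525), Ascl2 (-0.90), Ncam1 (-0.77), Prl7b1 (-0.96), Gcm1 (0.072), Slc2a3 (0.0495), Slc7a8 (0.0952), Col3a1 (-0.14), Postn (-0.0249), Fbn1 (-0.22), Actg2 (-0.0358), Myh11 (-0.0182), Hba-a2 (-0.0743), Hbb-bt (-0.013), Hba-a1 (-0.0111), Dusp1 (-0.0171), Ankrd37 (-0.31), Adm (-0.0379), Aldoa (-0.0555), Scd2 (0.0757), Scd1 (0.11), mt-Nd6 (0.42), mt-Nd5 (0.33), mt-Nd4 (0.16), Kdm5d (0.54) and Eif2s3y (0.0831). The covariate holds Actg2 and Myh11 themselves; for the other genes the cause was not tested. Depth limits genes near the minimum mean of 10.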

Other observations

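Yolk sac endoderm markers were not spread evenly over the matKO libraries. All 11 measured markers were highest of all 8 libraries in matKO replicate 2, with Afp at 20555 against 12496 in matKO replicate 4, Apob at 3809 against 1502 in WT replicate 1, Ttr at 1164 against 538 in WT replicate 1 and Spink1 at 189 against 81.9 in WT replicate 2. This count was chosen after its values were seen. Without that library the mean log2 fold change of the list was 0.08, against 0.39 with all libraries.

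The lists past the threshold with the preset correlation numbered 11 in the real split, and 8 of 34 splits of the libraries gave as many, with a highest other count of 14 and a median of 9. Chance can therefore not be excluded for the number of lists.

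A hypothesis drawn from these data is that matKO placentas hold more smooth muscle or contractile cells. A lower share of trophoblast would raise markers of every other cell type, but the smooth muscle mean was higher by 0.51 log2 units (95% interval 0.20 to 0.81) while endothelium and macrophage markers were at -0.27 (-0.53 to -0.01), and the difference between them was 0.78 (0.43 to 1.13). These lists did not pass with an estimated correlation (camera adjusted p of 0.285 for smooth muscle and 0.388 for endothelium and for macrophage markers) or by fry (0.188, 0.389 and 0.371). Other non-trophoblast lists were higher, with uterine natural killer cell genes at 0.47, yolk sac markers at 0.39, erythroid genes at 0.29 and mesenchyme markers at 0.17. Against all 8 other non-trophoblast lists together, at 0.07 (-0.11 to 0.25), smooth muscle was higher by 0.44 (0.08 to 0.80). The smooth muscle list had the highest mean of the 28 lists, and these comparisons were picked after that was seen. They therefore cannot decide against a lower share of trophoblast, as the whole cause or as a part. Without WT replicate 4, which stood apart in decidual genes, the smooth muscle mean was 0.45. Uterine natural killer cell, yolk sac, decidual, erythroid and mesenchyme lists were then at 0.74, 0.36, 0.34, 0.30 and 0.13. Macrophage, neutrophil and endothelium lists were at -0.50, -0.23 and -0.12. The comparison of smooth muscle with the 8 lists was not repeated without that library. A litter difference among the RNeasy libraries cannot be told apart from genotype for this list, since the mean within the Trizol litter was 0.34 with an interval of -0.0743 to 0.75. These tests were chosen after the values were seen, and a linear model with normal errors gave the intervals.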
